A study of Homo sapiens with 42 samples.

How the data were processed

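Poly(A) RNA of WT and ADIPOR2 KO HEK293T cells was sequenced in 42 libraries of 14 groups, 3 libraries each, prepared with a stranded mRNA kit and read in pairs on a NextSeq 500 according to the labels. Groups were taken from the labels: WT or KO in full medium, or 3, 9 or 24 h in serum-free medium with 1% BSA, without or with 200 µM PA. The PA was dissolved in DMSO before it was mixed with fatty-acid-free BSA, and the labels do not say whether the BSA medium received DMSO. A protocol entry also mentions 6 h, a time that no label of the 42 libraries carries. The deposited file held signal values for 59711 genes: per the submitters' processing notes, estimated counts from Salmon on hg38 were rounded and divided by 1 size factor per library from DESeq2. Tool versions, the transcript annotation, any filters and the use of read strand are not given in the sources used here, so overlapping and antisense genes are uncertain, as are paralogs and pseudogenes.

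Each of the 42 value columns was matched to a sample, 3238 genes had no symbol and 15745 genes were 0 in every library. The values of each of the 42 libraries were multiples of 1 step, and 100% of the values up to 1000 reads were whole within 0.001. In KO BSA 9 h replicate 1 and KO PA 24 h replicate 3 the step was close to 1 (size factors of 1.01 and 0.998). By a choice made before testing, whole reads of these 2 were left out of the count test, which used the other 40, but the depth given here includes them. Recovered depth was 15.2 to 31.2 M reads per library, and the size factors were 0.718 to 1.44. A count of 10 reads has a Poisson error of about 32% and a count of 1000 about 3%. Libraries of the same group correlated at 0.970 or above on the log2 scale. KO BSA 24 h replicate 1 and KO PA 9 h replicate 1 stood apart from their partners. Their chi-square of whole reads per degree of freedom was 21.5 to 26.4, against 4.40 to 12.7 in the other pairs.

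Values were compared as log2(value + 1) with limma-trend (limma 3.58.1 in R 4.3.3), a moderated t test. A single model with a mean for each of the 14 groups was fitted to all 42 libraries. Genes with a value of at least 10 in at least 3 libraries were tested (19272 genes, 19040 with a symbol), with two-sided p-values adjusted by the Benjamini-Hochberg method over genes within each comparison and called below 0.05. The 23 comparisons were PA against BSA at each time and genotype, the difference of these responses between genotypes (an interaction), KO against WT in each condition and in the mean over 7 conditions, and BSA against full medium. In this mean, 21 libraries stood on each side. In the tables of a difference of responses, calls are the interaction itself. Mean values are given with SD, and log2 values with the standard error of the model. The p-values of all lists and genes in the text come from limma, apart from those said to come from edgeR.

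Gene lists, 22 in number, were fixed before the data were examined. Each was tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. The members that passed were counted over all genes tested and adjusted over the list alone. The text names ADIPOR2, members of the lists with the smallest p (4 per list), and the largest changes by a rule written before the data were examined. That rule took genes with adjusted p below 0.05 whose 3 libraries in one group all lay beyond the 3 of the other (for a difference of responses, the adjusted p of the interaction alone), with a mean of at least 50 in the higher group and a symbol that is not a readthrough or clone name, the 10 largest in each direction. Not every such gene is named in the text. One gene of this selection in the region shared by the sex chromosomes was left out. No fold change is given in the report for a gene listed at 0 in every library of a group compared. The closing section prints fitted differences for 3 such genes, which depend on the pseudocount. Gene positions are those of GENCODE v29 on GRCh38, and 283 tested genes had none.

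The count test used edgeR 4.0.16 (quasi-likelihood) on the whole reads of 40 libraries with the same model. It called 1958, 5224 and 10306 genes for PA against BSA in WT at 3, 9 and 24 h, 2279, 5193 and 8742 in KO, and 3, 325 and 4858 for the difference. The other alternatives were pseudocounts of 0.5 and 5, no filter, no trend, quantile normalization, rescaling to the same total, a fit of only the groups compared, sample weights, a replicate block and leaving out each library in turn. A restriction to genes with a mean of at least 50 was added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.

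The test was tried on simulated data for PA against BSA in WT at 3 h alone. With 50 genes changed at each size, limma recovered 38, 92, 100 and 100% of changes of 1.25, 1.5, 2 and 4-fold, and edgeR 38, 88, 100 and 100%. In 10 simulations the false share among limma calls was 12.05% on average (10.68 to 14.35%) against the nominal 5%, and 5.21% among genes with a mean of at least 50. In a single simulation it was 3.21% for edgeR. The other comparisons were not simulated, so the false share of their counts was not measured. Of 200 random lists, 2 had p below 0.05 with camera and 10 with fry.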

Results

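Poly(A) RNA was sequenced from HEK293T cells, a human embryonic kidney line that carries adenovirus DNA and the SV40 large T antigen. The cells were either wild type (WT) or knocked out for ADIPOR2 (KO), which encodes a membrane protein of the progestin and adipoQ receptor (PAQR) family that binds adiponectin. Both genotypes were sampled in full medium with 10% fetal bovine serum. They were also sampled after 3, 9 and 24 h in serum-free medium with 1% bovine serum albumin (BSA), and after 3, 9 and 24 h in that medium with 200 µM palmitic acid (PA), a saturated fatty acid carried by albumin. The 42 libraries formed 14 groups of 3. Recovered depth was 15.2 to 31.2 M reads per library (median 21.9 M). Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Nor do the labels give the number of KO clones, so genotype and clone were not separated.

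Every log2 value given here is a difference of mean log2(normalized value + 1), which understates the change of genes with low values. Errors of log2 values are standard errors, and n was 3 libraries per group unless stated otherwise. List counts are over all genes tested, and the counts adjusted over the list alone are given where they differ. For genes named by the rule of largest change in a comparison of 2 groups, all 3 libraries of one group lay beyond all 3 of the other. On the first principal component (17.1% of the variance), the 24 h BSA libraries stood apart from the rest, with mean scores of 89.4 in WT and 69.4 in KO. The corresponding 24 h PA libraries scored -4.41 in WT and 16.6 in KO, and full medium -27.9 and -19.9. The second component (13.1%) separated the genotypes, with every WT group mean at or above 13.6 and every KO group mean at or below -15.0.

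**Figure D1:**
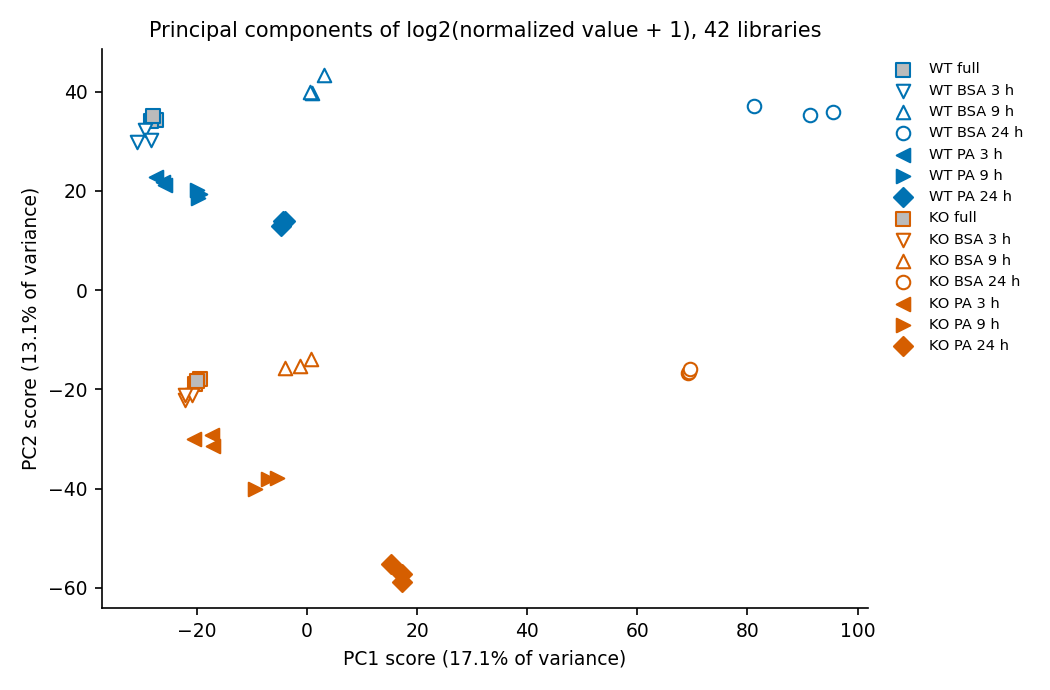
Scores of the 42 libraries on principal components 1 and 2 (log2 scale, arbitrary units), with 1 point per library and colours and symbols for genotype and medium. The 24 h BSA libraries lie far to one side on component 1, and component 2 parts WT from KO.

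The knocked-out gene was examined first, as a check of the labels. ADIPOR2 (ENSG00000006831) is a protein-coding gene on the plus strand of chromosome 12 at 1688574 to 1788678 (GRCh38). Its transcript was still present in KO cells, at 79.9% of the WT level averaged over the 7 conditions (log2 difference -0.32 ± 0.01, adjusted p = 6.9e-22 by limma). In full medium the normalized value was 3440 ± 55.3 in WT and 2940 ± 106 in KO (mean ± SD). In BSA medium it was 3587 ± 5.67, 3985 ± 69.4 and 4904 ± 127 in WT at 3, 9 and 24 h, against 2835 ± 46.9, 3057 ± 91.5 and 3528 ± 64.0 in KO. In PA medium it was 4128 ± 143, 4048 ± 37.5 and 3539 ± 69.1 in WT, against 3392 ± 44.8, 3420 ± 92.3 and 2913 ± 23.1 in KO. In each condition the 3 KO libraries lay below the 3 WT libraries, and the KO level was 71.9 to 85.5% of WT. With PA at 24 h, ADIPOR2 fell by 0.47 on the log2 scale in WT (adjusted p = 1.3e-14) and by 0.28 in KO. The edit itself is not described in the labels, and a gene-level transcript value does not test whether the protein was lost. The 40 nearest tested genes, between 14522 and 4615302 on chromosome 12, had a median KO minus WT difference of -0.20, and 10 of them were lower relative to WT than ADIPOR2.

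**Figure D2:**
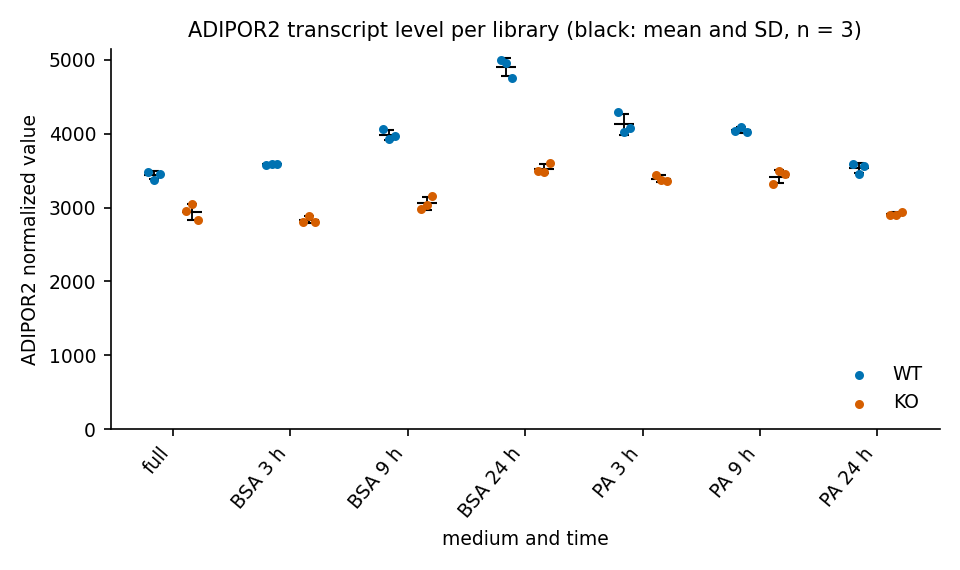
Normalized value of ADIPOR2 (linear axis from 0, size-factor normalized reads) in each of the 14 groups, with points for single libraries and a bar for the mean ± SD. KO libraries lie below the WT libraries of the same medium and time, with means between 2835 and 3528.

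The comparison of PA with BSA medium asked how cells respond to a saturated fatty acid. A rise or fall here is against BSA medium at the same time, which itself differed from full medium as given further below. At 3 h, genes of the integrated stress response, the programme run by the transcription factor ATF4, rose in both genotypes. CHAC1, a glutathione-degrading enzyme of that programme, rose by 1.43 ± 0.16 in WT (443 against 164) and 2.43 ± 0.16 in KO (377 against 70.4). SESN2, a stress-induced inhibitor of mTORC1, rose by 0.82 ± 0.07 in WT, and ATF4 itself by 0.46 ± 0.04 in KO. JUN, an immediate early transcription factor, rose by 0.64 ± 0.05 in WT and 0.83 ± 0.05 in KO. Among genes that fell, CYP26A1, which degrades retinoic acid, fell by 1.48 in WT and 1.83 in KO. DHRS3, a retinal reductase, fell by 1.49 in WT and RARB, a retinoic acid receptor, by 1.44 in KO. The largest rises in WT also included NBR2, TNFSF4 and NGFR, and the largest falls SFT2D3, CDH7, C11orf45, TMEM100 and S1PR1. LDLRAD2 stood at 62.0, 83.8 and 125 in the WT libraries with PA and at 1.38, 0 and 0 with BSA, and a single KO library with BSA at 24 h reached 188.

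Of the 31 measured genes of the stress response list, 21 rose and 0 fell in WT at 3 h over all genes tested (23 and 0 adjusted over the list alone), with a median of 0.32 (adjusted p = 9.3e-19). In KO 18 rose and 2 fell (20 and 3 adjusted over the list alone), with a median of 0.31. Replication-dependent histone genes had a median of 0.54 in WT (adjusted p = 0.00052) and 0.44 in KO (adjusted p = 0.0031). Those calls were not made with an estimated correlation (adjusted p = 0.35 in WT and adjusted p = 0.52 in KO with an estimated correlation). The histone list is uncertain in every comparison of this report, both for its near-identical copies and because poly(A) RNA was sequenced. In all, 2192 genes passed the test in WT (1025 higher and 1167 lower, 70 and 152 of them at least 2-fold) and 2258 in KO (1073 and 1185). The WT count fell to 493 when only the groups compared entered the fit, and the KO count to 1196. Rescaling every library to the same total gave 736 higher and 1456 lower genes in WT.

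By 9 h the stress response was larger. ATF3, a transcription factor of that response, rose by 2.01 ± 0.11 in WT (2843 against 709) and 2.73 ± 0.11 in KO (5583 against 839). SLC7A11, the cystine transporter, rose by 2.93 ± 0.11 in KO (4426 against 580), and ASNS, asparagine synthetase, by 1.66 ± 0.06. The main chaperone of the endoplasmic reticulum (ER), HSPA5, rose by 0.79 ± 0.05 in KO, and the ER degradation factor HERPUD1 by 1.18 ± 0.07 in WT and 1.80 ± 0.07 in KO. Genes of sterol synthesis and uptake fell together against BSA medium, in which the same list was higher than in full medium at 9 h. INSIG1, which retains the sterol regulator SREBP2 in the ER, fell by 0.54 in WT and 0.84 in KO. SCD, the desaturase that makes monounsaturated fatty acids, fell by 0.25 in WT and 0.43 in KO.

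Among the largest changes in WT at 9 h, ZNF619 rose by 3.91 ± 0.19, C1GALT1C1L by 2.33, HLF by 2.23, ZSCAN26 by 2.15, ZNF22 by 2.09, IFT46 by 2.08 and CHAC1 by 2.04. GRIK4 fell by 2.53, the Hedgehog effector GLI1 by 2.46, GALR2 by 2.13, GOLGA7B by 1.98, GAS2L1 by 1.78, TCEAL3 by 1.71, TNXB by 1.61 and CCBE1 by 1.59. The WT BSA libraries differed widely for GRIK4 (141 ± 107, mean ± SD) and GLI1 (55.7 ± 30.2). In KO the largest rises included CHAC1 (2.82), ZNF619 (2.75), the mitochondrial enzyme PCK2 (2.16 ± 0.11) and the secreted glycoprotein STC2 (2.16 ± 0.16). IFIT1, an interferon-induced gene, fell by 1.94 ± 0.16 in KO, GOLGA7B by 1.66, GAS2L1 by 1.58 and HOXA2 by 1.52, together with S1PR1 and NTNG2. Named genes that share sequence with relatives or overlap other transcripts are uncertain: MT1X, ASNSP1, ZBTB11-AS1, MIR210HG and ZNF503-AS2 in WT, and RNU1-1, ASNSP1, HIST2H4B, HIST1H1E, SMIM11A, ZNF503-AS2 and HOXA-AS3 in KO. RNU1-1 had a mean of 580 with an SD of 961 in KO with PA, so its libraries differed widely. HIST2H2AA3 was listed at 0 in all 3 KO PA libraries.

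In WT at 9 h, 30 of 31 stress response genes rose and 1 fell, over all genes and adjusted over the list alone, with a median of 0.84 (adjusted p = 6.3e-37). In KO 29 rose and 0 fell (30 and 1 adjusted over the list alone), with a median of 1.39. Of 24 measured sterol genes, 14 fell and 1 rose in WT (median -0.25, adjusted p = 1.7e-09), and 19 fell and 0 rose in KO (median -0.40). Adjusted over the list alone, 15 fell in WT and 20 in KO. Of 24 genes of fatty acid synthesis and desaturation, 13 fell and 1 rose in WT (median -0.20, adjusted p = 0.0001), and 11 fell and 3 rose in KO (13 and 3 adjusted over the list alone, median -0.19). ER chaperone and degradation genes rose in KO (16 of 24, 0 fell, 16 and 1 adjusted over the list alone, median 0.31, adjusted p = 1e-08). In WT 9 rose and 3 fell (10 and 3 adjusted over the list alone, median 0.13, adjusted p = 0.0016, but adjusted p = 0.19 with an estimated correlation). Heat shock genes fell in both genotypes (10 of 18 in WT and 12 in KO, 11 and 13 adjusted over the list alone, adjusted p = 0.00047 and 2.1e-05), calls that were lost with an estimated correlation (adjusted p = 0.22 and adjusted p = 0.1 with an estimated correlation). The test called 5236 genes in WT (2712 higher and 2524 lower) and 5815 in KO (2871 and 2944).

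At 24 h the ER response was the largest list change in KO. HSPA5 rose by 2.54 ± 0.05 in KO (71805 against 12316) and by 1.40 ± 0.05 in WT (24085 against 9118). PDIA4, a disulfide isomerase of the ER, rose by 2.13 ± 0.04 in KO and 0.87 ± 0.04 in WT. ATF3 rose by 2.55 ± 0.11 in KO (13129 against 2254), HERPUD1 by 2.34 ± 0.07 and PPP1R15A, which restores translation after stress, by 2.27 ± 0.09. The stress response list went both ways in WT: ATF5 rose by 1.77 ± 0.09 and WARS by 0.74 ± 0.05, while the serine and glycine enzymes SHMT2 and PHGDH fell by 0.79 and 0.61. SCD fell by 1.38 in KO (10446 against 27149) and by 0.74 in WT, and NSDHL, an enzyme of cholesterol synthesis, by 1.52 in KO and 1.48 in WT.

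**Figure D3:**
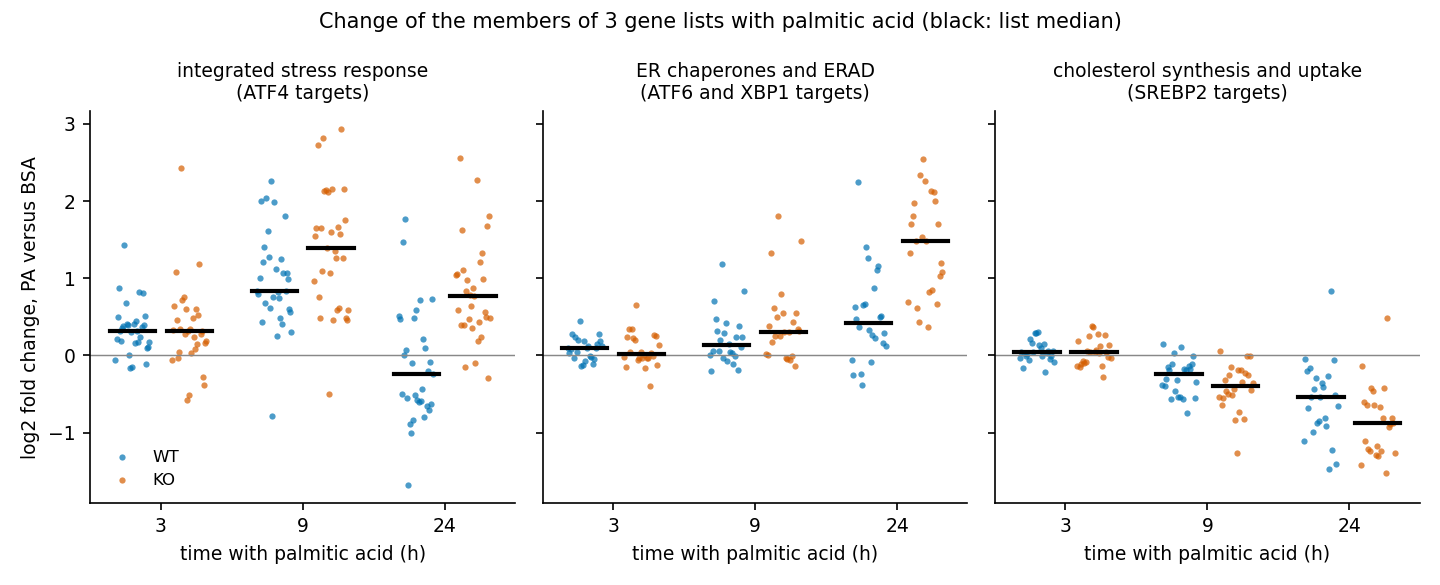
Log2 fold change (PA against BSA, 3 libraries per group) of each measured member of the integrated stress response, ER and sterol lists at 3, 9 and 24 h in WT and KO, with a black mark for the list median. Medians of the stress response list were 0.84 in WT and 1.39 in KO at 9 h, and those of the ER list 0.42 and 1.49 at 24 h.

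All 24 ER genes rose in KO at 24 h (median 1.49, adjusted p = 1.7e-23). In WT 18 rose and 3 fell (18 and 4 adjusted over the list alone), with a median of 0.42 and adjusted p = 5e-05, but adjusted p = 0.071 with an estimated correlation. Of the 31 stress response genes, 26 rose and 1 fell in KO (26 and 2 adjusted over the list alone, median 0.77, adjusted p = 4.4e-12). In WT 7 rose and 16 fell (8 and 16 adjusted over the list alone), and the list did not pass the test (median -0.24, adjusted p = 0.078). Sterol genes fell in both genotypes, 23 of 24 in KO (median -0.88, adjusted p = 2e-17) and 20 in WT (21 adjusted over the list alone, median -0.53, adjusted p = 2e-09), with 1 rising in each. In KO 13 genes of fatty acid synthesis fell and 1 rose (median -0.39, adjusted p = 5.7e-05). In WT 13 fell and 4 rose (13 and 6 adjusted over the list alone, median -0.18, adjusted p = 0.046, but adjusted p = 0.071 with an estimated correlation), and ACLY, which makes cytosolic acetyl-CoA, fell by 1.09.

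Immediate early and serum response genes rose in KO at 24 h (24 of 30, 4 fell, 25 and 4 adjusted over the list alone, median 1.20, adjusted p = 1.3e-06), led by EGR1 at 4.71 ± 0.19 (5157 against 199). EGR1 rose by 3.28 ± 0.19 in WT, where the list did not pass (median 0.46, adjusted p = 0.2). NF-kB and inflammatory genes rose in KO (13 of 17, 1 fell, median 1.32, adjusted p = 0.00028), and in WT 8 rose and 1 fell (median 0.77, adjusted p = 0.11). Lysosome and autophagy genes fell in WT (18 of 29, 3 rose, median -0.30, adjusted p = 6e-05) and KO (14, 3 rose, median -0.29, adjusted p = 0.0012). LAMP1, a lysosomal membrane protein, fell by 1.24 in WT and 1.33 in KO. In KO the adiponectin and PAQR list fell (7 of 13, 0 rose, 7 and 1 adjusted over the list alone, median -0.31, adjusted p = 0.015). In WT 5 rose and 6 fell (median -0.36, adjusted p = 0.3). S phase genes fell in KO (19 of 29, 3 rose, median -0.37, adjusted p = 2.4e-05). In WT 16 fell and 4 rose (median -0.22, adjusted p = 0.0042, but adjusted p = 0.27 with an estimated correlation).

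Several lists passed only with the preset correlation at 24 h. G2/M genes rose in WT (16 of 25, 3 fell, median 0.13, adjusted p = 0.018) and KO (14, 4 fell, median 0.17, adjusted p = 0.015), with adjusted p = 0.38 and adjusted p = 0.32 with an estimated correlation. BIRC5, a mitotic survivin, rose by 1.44 ± 0.05 in WT and 1.12 ± 0.05 in KO. Heat shock genes fell in WT (13 of 18, 4 rose, median -0.40, adjusted p = 0.0064) and KO (10, 3 rose, median -0.19, adjusted p = 0.028), with adjusted p = 0.34 and adjusted p = 0.4 with an estimated correlation. FOXO targets fell in WT (11 of 20, 3 rose, median -0.33, adjusted p = 0.0067, but adjusted p = 0.14 with an estimated correlation), and in KO 9 fell and 4 rose (median -0.25, adjusted p = 0.25). Hypoxia and glycolysis genes fell in KO (13 of 22, 3 rose, 14 and 5 adjusted over the list alone, median -0.44, adjusted p = 0.00045, but adjusted p = 0.21 with an estimated correlation), and in WT 10 fell and 5 rose (10 and 6 adjusted over the list alone, median -0.15, adjusted p = 0.2).

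The remaining lists did not pass at 24 h in either genotype. Of 26 genes of fatty acid oxidation, 7 rose and 7 fell in WT (7 and 8 adjusted over the list alone, median 0.00, adjusted p = 0.73), and 3 rose and 12 fell in KO (median -0.14, adjusted p = 0.075). ACADVL, which oxidises very long chain fatty acids in mitochondria, rose by 2.53 ± 0.08 in WT (2328 against 405) and 2.22 ± 0.08 in KO. In WT, ACADVL was itself lower with BSA than in full medium at 24 h. The list medians were 0.39 in WT and -0.03 in KO for 21 glycerolipid genes, -0.02 and 0.05 for 28 phospholipid genes, and -0.06 and 0.02 for 34 sphingolipid genes (adjusted p from 0.37 to 0.89). In WT 10, 13 and 8 of these rose and 5, 8 and 12 fell, and in KO 6, 10 and 9 rose and 7, 9 and 12 fell. Adjusted over the list alone the counts were 11 and 5 for glycerolipid genes in WT, 12 and 11 for phospholipid genes in KO and 10 and 13 for sphingolipid genes in KO. Medians were 0.14 and 0.21 for 23 apoptosis and p53 genes, and -0.12 and 0.00 for 20 oxidative stress genes (adjusted p from 0.15 to 0.86). Of the former 7 rose and 7 fell in WT (7 and 8 adjusted over the list alone) and 12 rose and 6 fell in KO, and of the latter 3 rose and 8 fell in WT and 8 rose and 7 fell in KO. HMOX1, which degrades haem, rose by 1.55 ± 0.11 in WT and 2.98 ± 0.11 in KO. Medians were -0.03 and 0.09 for 13 mitochondrially encoded mRNAs and -0.43 and 0.29 for 20 histone genes (adjusted p from 0.2 to 0.89). Among histone genes 0 rose and 6 fell in WT and 4 rose and 3 fell in KO (2 and 3 adjusted over the list alone), and 1 mitochondrial mRNA fell in each genotype (0 in KO adjusted over the list alone). Of 15 measured markers of other cell types, 4 rose and 1 fell in WT and 3 rose and 1 fell in KO (3 and 1, and 2 and 1, adjusted over the list alone, medians -0.08 and -0.14, adjusted p = 0.76 and 0.89). ACTA2, a smooth muscle actin, rose by 1.64 ± 0.20 in WT and 1.51 ± 0.20 in KO. The median and the test differed in sign for the phospholipid list and the markers of other cell types in both genotypes, and for the sphingolipid list in KO. Rescaling to the same total or quantile normalization turned the sign of the WT median of the fatty acid oxidation, phospholipid, sphingolipid and mitochondrial lists, and of the KO median of the sphingolipid and oxidative stress lists.

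Among the largest changes in WT at 24 h, CXCL8, a neutrophil chemokine, rose by 4.52 ± 0.38 (171 against 6.65) and the receptor TNFRSF9 by 4.13 ± 0.40. COQ3, an enzyme of ubiquinone synthesis, rose by 3.83 ± 0.12 (515 against 35.9). The others were GGACT (4.94 ± 0.24), SLC6A17, KLHDC9, C1GALT1C1L, PIP5K1B, CSRP1 (3.66 ± 0.18) and SLC25A48. TNFRSF8 fell by 6.27 in WT (1.19 against 149), CIB3 by 5.97, MISP, an actin-bundling mitotic protein, by 5.64, PRRG2 by 5.62, CLEC17A by 5.13 and DOCK2 by 5.07, as did the noncoding RPL34-AS1 by 4.95. MUC12 and MIR5188 were listed at 0 in all 3 WT PA libraries. The MUC12 values with BSA were 39.7, 88.3 and 36.3, and those of MIR5188 were 45.1, 69.4 and 49.7. In WT full medium the means were 689 for COQ3, 109 for GGACT, 262 for CSRP1 and 1.75 for TNFRSF8. These lay nearer to the PA than to the BSA values. Full-medium means of the other genes named in this paragraph are not listed here.

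In KO at 24 h CXCL8 rose by 5.04 ± 0.38 (902 against 27.3), and FOS, an immediate early gene, by 4.18 ± 0.40 (898 against 49.2). The other large rises were MMP10, a matrix metalloproteinase (4.67), C11orf96 (4.35), the activin subunit INHBA (4.33), ARC (4.03), KCNA1 (3.85), SPRY4 (3.60) and GEM (3.59). MISP (-5.12 ± 0.69), TNFRSF8 (-4.96 ± 0.56), ZNF556 (-4.29), PRRG2 (-4.11), KIF17 (-3.55 ± 0.37) and PLTP, a phospholipid transfer protein (-2.88), fell most. Among noncoding and pseudogene transcripts, which are uncertain, AFAP1-AS1 fell by 4.28, ZRSR1 by 4.07, LINC01234 by 3.50 and SNHG14 by 3.47. The KO BSA libraries differed widely for AFAP1-AS1 (121 ± 151, mean ± SD) and KCNA1 (13.5 ± 21.3).

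The test called 10313 genes in WT at 24 h (5178 higher and 5135 lower, or 5909 and 4282 when rescaled to the same total; 1932 and 1053 were at least 2-fold) and 9595 in KO (4891 and 4704, or 5091 and 4483 rescaled; 1477 and 948 at least 2-fold). Of the genes called before rescaling, 3281 were higher and 3104 lower in both genotypes, against 1314 and 1253 for independent lists, and 530 were called in opposite directions. The controls of the genotypes were different libraries. At 9 h 1765 were higher and 1682 lower in both (404 and 386 if independent), and at 3 h 509 and 595 (57.1 and 71.8).

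The difference between the PA responses of KO and WT asked whether loss of ADIPOR2 changes the response to the fatty acid. At 24 h ER genes rose further in KO: PDIA4 by 1.26 ± 0.06, HSPA5 by 1.14 ± 0.06 and HERPUD1 by 1.69 ± 0.11 on the log2 scale. Stress response genes also had higher responses in KO, with differences of 1.98 ± 0.12 for DDIT3, which encodes the transcription factor CHOP, and 1.76 ± 0.13 for TRIB3, a pseudokinase induced by it. GADD45B, a growth arrest gene, differed by 2.39 ± 0.24, IER3 by 1.70 ± 0.16 and CTGF, a matricellular growth factor, by 2.47 ± 0.28. SCD, a fatty acid desaturase, and INSIG1 each fell further in KO, by 0.64. FADS2, another desaturase, and SQLE, of sterol synthesis, differed by -0.97 ± 0.10 and -0.83 ± 0.08, and neither passed in WT alone. PGK1 and LDHA, both enzymes of glycolysis, differed by -0.98 ± 0.10 and -0.64 ± 0.07.

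**Figure D4:**
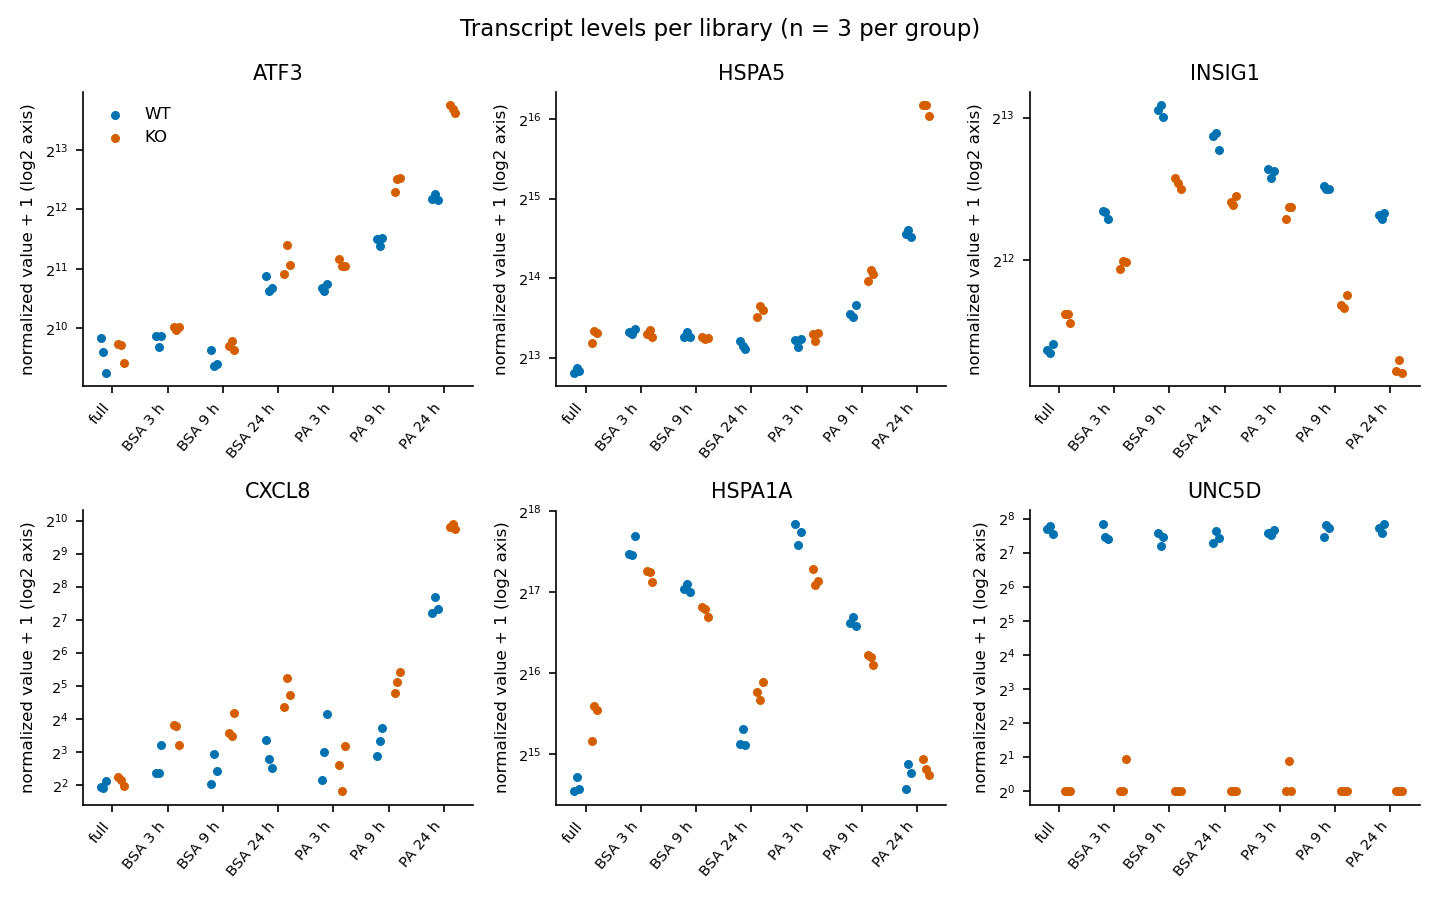
Normalized values + 1 (log2 axis, size-factor normalized reads) of ATF3, HSPA5, INSIG1, CXCL8, HSPA1A and UNC5D in the 14 groups, with 1 point per library. HSPA5 is highest in KO with PA at 24 h (mean 71805), and UNC5D is near 0 in the KO groups.

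A higher response here is a more positive log2 change with PA, which need not be a larger one. Of 24 ER genes, 22 had a higher PA response in KO at 24 h and 0 a lower one (23 and 1 adjusted over the list alone, median difference 0.94, adjusted p = 6.3e-28). Of 31 stress response genes, 26 had a higher and 0 a lower one (28 and 0 adjusted over the list alone, median 1.00, adjusted p = 7.7e-29). In WT more genes of this list fell than rose with PA at 24 h, so the difference includes falls in WT. Immediate early genes had higher responses in KO (13 of 30, 1 lower, 14 and 2 adjusted over the list alone, median 0.85, adjusted p = 1.5e-05). The sterol list was lower in KO (14 of 24, 2 higher, 15 and 2 adjusted over the list alone, median -0.30, adjusted p = 7.6e-06), as was fatty acid synthesis (8 of 24, 1 higher, median -0.17, adjusted p = 0.0046). A further 5 lists passed only with the preset correlation. Their median differences were -0.22 for fatty acid oxidation, 0.52 for NF-kB, 0.26 for FOXO targets, -0.35 for hypoxia and glycolysis, and 0.77 for histone genes. They had adjusted p = 0.072, adjusted p = 0.13, adjusted p = 0.068, adjusted p = 0.24 and adjusted p = 0.37 with an estimated correlation, in that order.

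Among the 20 largest differences at 24 h, protein-coding genes with no group listed at 0 were DHRS2, a mitochondrial reductase (3.24 ± 0.38), ACSBG1, an acyl-CoA synthetase (3.06 ± 0.84), and RASD1 (3.01 ± 0.57), with higher responses to PA in KO. KCNH1 (-3.69 ± 1.24), MAP2K6, a kinase of the p38 pathway (-2.89 ± 0.40), MRAP2 (-2.74 ± 0.30) and TMEM255A (-2.73 ± 0.22) had lower responses in KO. Features among the 20 largest that are noncoding, tRNA genes or close copies of other genes are uncertain: LINC02158, FAM157B, LINC00923, CEACAMP10, LINC01554, MIR5188, GK3P, AFAP1-AS1, MT-TA, MT-TN, MT-TC and MT-TY. MUC12 was listed at 0 in KO with BSA and with PA at 24 h, and in WT with PA. GK3P was listed at 0 in WT with BSA and MIR5188 in WT with PA. In all 5268 genes had a different response at 24 h, 2412 higher and 2856 lower in KO (1916 and 3413 when rescaled to the same total). ADIPOR2 was among them (0.19 ± 0.05, adjusted p = 0.0015).

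At 9 h the difference was smaller and had the same direction for the stress, ER and sterol lists. SLC7A11 differed by 1.13 ± 0.15, STC2 by 1.09 ± 0.23, PCK2 by 1.04 ± 0.16, DDIT3 by 0.87 ± 0.12 and HSPA5 by 0.50 ± 0.06. SULT4A1, CLEC2D, RELB, RAB39B, CALCB and IER3 also had higher responses in KO, as did the noncoding CASC2. EXO5 (-1.10 ± 0.14), ZNF503 (-0.98 ± 0.08), ZNF619, ZNF496, UQCC3, C4orf48, SCARA3, TMC6, PCOLCE2 and ZBTB11-AS1 had lower ones. Of the stress response list, 18 genes had higher and 1 a lower response in KO (22 and 1 adjusted over the list alone, median 0.42, adjusted p = 1e-25). Of the ER list 5 had higher and 0 lower ones (10 and 2 adjusted over the list alone, median 0.21, adjusted p = 2.7e-08). The sterol list fell with PA in both genotypes, and 4 of its genes had lower and 0 higher responses in KO (5 and 0 adjusted over the list alone, median -0.14, adjusted p = 3.5e-05). By the median this was a larger fall in KO. NF-kB genes (median 0.38, adjusted p = 0.0044) and FOXO targets (median 0.22, adjusted p = 5.5e-05) had higher differences, with 2 genes called in each list (2 and 3 adjusted over the list alone). S phase, mitochondrial and histone lists passed with medians of -0.06, -0.30 and 0.38, but had adjusted p = 0.36, adjusted p = 0.68 and adjusted p = 0.37 with an estimated correlation.

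The 9 h count was 402 genes (158 higher and 244 lower), and it was 199 without WT BSA 9 h replicate 1, 223 without the filter on low values, 260 when only the groups compared entered the fit and 864 with sample weights. At 3 h the test called 3 genes, all with lower responses in KO: ZNF503 (-0.56 ± 0.08, adjusted p = 0.0012), ATP5E, a subunit of ATP synthase (-0.80 ± 0.13, adjusted p = 0.0029), and ENSG00000205246 (-0.83 ± 0.12, adjusted p = 0.0012), which has no symbol in the deposited table and was named after its value was seen. No list passed at 3 h. In limma 1398 genes had an unadjusted p under 0.05, the count test in edgeR also called 3, and 29 genes were called without WT BSA 3 h replicate 3.

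The comparison of KO with WT cells asked which transcripts differ with genotype in any medium. In the mean over 7 conditions, the largest differences were genes lower in KO. UNC5D, a netrin receptor, had a mean of 0.084 in KO against 191 in WT and was listed at 0 in 19 of 21 KO libraries. FLRT2, an adhesion protein, was lower by -6.10 ± 0.19 (14.4 against 875) and NEFM, a neurofilament subunit, by -6.06 ± 0.16. SOX11, a developmental transcription factor, differed by -4.79 ± 0.14 (6.13 against 186), CNTN4 by -5.17, SPARC, a matrix glycoprotein, by -4.85, CDH11 by -4.34 and PSMD5 by -4.28. ARMCX2 was listed at 0 in all libraries of 4 KO groups. Higher in KO were several zinc finger genes of chromosome 19, ZNF730 (4.14 ± 0.20), ZNF671 (4.10 ± 0.15), ZIK1 (2.46 ± 0.10), ZNF433 (2.33) and ZNF91 (2.05), together with BCAN (3.67) and PCDHB2 (2.38). The pseudogenes DUXAP10, DUXAP9 and NBEAP3 were also higher and are uncertain.

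Sterol genes were lower in KO (20 of 24, 2 higher, median -0.26, adjusted p = 3e-10). Fatty acid synthesis passed as lower (11 of 24, 4 higher, median -0.05, adjusted p = 0.021), but when rescaled to the same total its median was -0.00396, with 8 lower and 6 higher, so the size and split depended on scaling. FADS2 differed by -0.85 ± 0.03 and SCD by -0.35 ± 0.01, while FDFT1 (-1.01 ± 0.02) lies in a segment of chromosome 8 where most genes were lower. Hypoxia and glycolysis genes were lower (18 of 22, 1 higher, median -0.38, adjusted p = 3e-10), led by NDRG1 at -1.86 ± 0.03. Another 6 lists passed with the preset correlation alone. ER genes (median 0.23), G2/M genes (0.12), NF-kB genes (0.46) and lysosome genes (0.12) were higher, and stress response genes (-0.22) and fatty acid oxidation (-0.06, or -0.00977 when rescaled to the same total) lower. They had adjusted p = 0.067, adjusted p = 0.097, adjusted p = 0.076, adjusted p = 0.16, adjusted p = 0.29 and adjusted p = 0.2 with an estimated correlation, in that order. Histone genes (median 0.55, adjusted p = 0.24 with an estimated correlation) and the adiponectin and PAQR list, which holds ADIPOR2 (median -0.16, adjusted p = 0.076 with an estimated correlation), did likewise. Among markers of other cell types, ACTA2 was lower in KO by -0.89 ± 0.08.

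In total 10845 genes differed in the mean over 7 conditions (5876 higher and 4969 lower in KO), of which 177 and 344 differed at least 2-fold. Single conditions gave 5084 in full medium, 3907, 4649 and 6235 with BSA, and 4161, 5281 and 7759 with PA at 3, 9 and 24 h. Rescaling to the same total gave 7271 higher and 4072 lower genes in the mean over 7 conditions (5876 and 4969 without it). It moved the share of higher genes by over 10 points in 5 single conditions: to 2645 higher and 1724 lower with BSA at 3 h (1763 and 2144 without it), 3409 and 1876 at 9 h (2264 and 2385), and 4244 and 2308 at 24 h (3333 and 2902). With PA it gave 3446 and 1673 at 3 h (1820 and 2341) and 3713 and 2138 at 9 h (2469 and 2812).

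Genes lower in KO were grouped along the genome. On chromosome 8 between 213186 and 30913003, 170 genes had a median difference of -0.70, and 94.7% of them were below 0. On chromosome 17 between 64099 and 19446852, 331 genes had a median of -0.49 (88.8% below 0). Shorter runs lay on chromosome 22 at 41688939 to 46010777 (65 genes, -0.36) and 50217689 to 50801309 (26 genes, -0.37), and on chromosome 14 at 103682362 to 106521073 (41 genes, -0.37). These runs held at least 25 genes; in scattered shorter ones, windows reached -0.33 on chromosome 12 (47 genes between 53500921 and 57547331) and, higher in KO, 0.35 on chromosome 19 (39 genes between 11797667 and 53444670). Whole chromosomes were lower as well: the median was -0.17 on chromosome 12, which carries ADIPOR2 (79.9% of 1005 genes below 0), -0.23 on chromosome 14 (86.9% of 613) and -0.26 on chromosome 22 (86.2% of 494). In each condition the median of the chromosome 8 run lay between -0.72 and -0.66. NEFM, FDFT1 and CTSB lie in the chromosome 8 run and UNC5D does not.

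**Figure D5:**
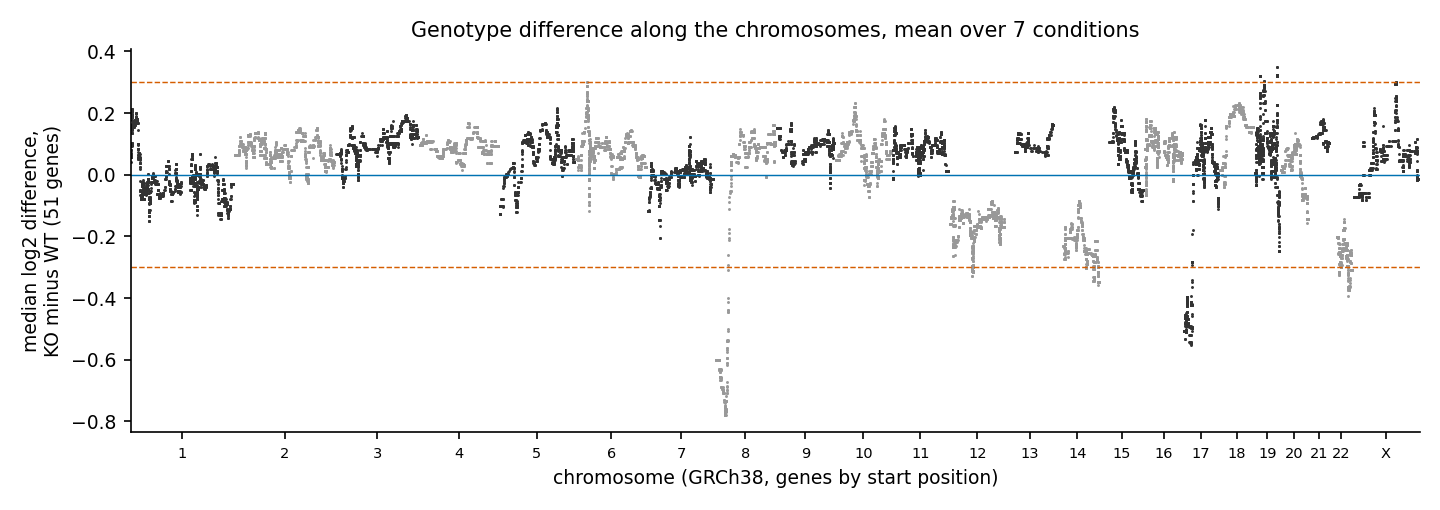
Median log2 difference (KO minus WT, mean over 7 conditions) in windows of 51 neighbouring tested genes, along each chromosome in GRCh38 position (Mb), with dashed lines at 0.3 and -0.3. Windows reach -0.78 at their lowest, and the longest runs below -0.3 lie on chromosomes 8 and 17.

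Levels in serum-free BSA medium, the baseline of the PA comparisons, differed widely from those in full medium. The labels give the full-medium libraries no time, and the same libraries were the reference at 3, 9 and 24 h. Effects of the medium, of handling and of time in culture were therefore not separated. At 3 h heat shock genes led: HSPA1B rose by 3.04 ± 0.09 and HSPA1A by 2.94 ± 0.09 in WT, a near-identical pair whose reads cannot be told apart with certainty, and the constitutive chaperone HSPA8 by 1.81 ± 0.05 (49166 against 14057). TXNIP, an inhibitor of thioredoxin, rose by 2.33 ± 0.16, and INSIG1 by 0.95 ± 0.04. ID1 and ID3, targets of BMP signalling, fell by 1.61 and 1.51 in WT and by 1.94 and 2.05 in KO. Sterol genes rose at each time, 21, 23 and 22 of 24 in WT (medians 0.41, 0.87 and 1.03) and 17, 24 and 20 in KO (medians 0.25, 0.51 and 0.79; adjusted over the list alone 24 in WT at 9 h and 18 in KO at 3 h). All 6 of these calls held with an estimated correlation, the largest adjusted p being 0.0021. Heat shock genes rose in WT at 3 h (9 of 18, 0 fell, 11 and 0 adjusted over the list alone, median 0.19, adjusted p = 7.6e-19) and 9 h (16, 0 fell, median 0.58, adjusted p = 3.4e-19).

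At 24 h in BSA medium WT cells had higher stress response genes: DDIT3 rose by 3.39 ± 0.08 (2532 against 241) and TRIB3 by 2.85 ± 0.09. IDI1, of isoprenoid synthesis, rose by 1.95 ± 0.06, and ARRDC4, a FOXO and glucose-responsive arrestin, by 2.17 ± 0.08. PLK1, a mitotic kinase, fell by 1.32 and ACADVL by 2.42. The stress response list rose in WT (26 of 31, 3 fell, median 1.27, adjusted p = 7e-15) and KO (27, 3 fell, median 1.37). Lysosome genes (21 of 29, 3 fell, median 0.38, adjusted p = 4.2e-06) and FOXO targets (13 of 20, 1 fell, 13 and 2 adjusted over the list alone, median 0.57, adjusted p = 0.00012) rose in WT, and fatty acid synthesis had a median of 0.20 (12 rose and 3 fell, adjusted p = 0.017). ER genes, hypoxia genes and heat shock genes rose (medians 0.28, 0.40 and 0.39) and G2/M genes fell (median -0.23) with the preset correlation alone, with adjusted p = 0.085, adjusted p = 0.26, adjusted p = 0.27 and adjusted p = 0.18 with an estimated correlation.

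The largest rises in WT at 24 h in BSA medium were MISP (6.23 ± 0.69), TNFRSF8 (6.00 ± 0.56), CLEC17A (5.58), PRRG2 (5.16), CIB3 (4.95) and the noncoding LINC02158, LINC01554 and MIR5188. MUC12 was listed at 0 in all 3 full-medium libraries. GGACT fell by 4.97, COQ3 by 4.25 (35.9 against 689), CPS1, the first enzyme of the urea cycle, by 4.01, EFNB3 by 3.85, KLHDC9 by 3.83, VANGL2, of planar cell polarity, by 3.63, AGK, a mitochondrial lipid kinase, by 3.54 (143 against 1651), and CSRP1 and CNTNAP2 by 3.51. MT1X, a metallothionein with close paralogs, fell by 3.86. In KO at 24 h MISP rose by 6.18, TNFRSF8 by 5.11, DUOX2 by 4.90 and CHAC1 by 4.10 ± 0.16, and COQ3 fell by 3.68.

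The test called 2210, 5969 and 10958 genes in WT at 3, 9 and 24 h, and 3220, 4082 and 9513 in KO. With only the groups compared in the fit, the 3 h counts were 653 in WT and 918 in KO, and the KO 9 h count 2532. Rescaling to the same total gave 2397 higher and 3617 lower genes in WT at 9 h (3054 and 2915 without it). At 24 h in WT it moved the median of all genes from -0.015 to -0.115, a shift smaller than the list medians given here.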

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

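The results in this part were marked because the response to PA differed between KO and WT by a test of the difference itself (the interaction in limma). The rule was written before the data were examined, while the regrouping of residuals, the tests of distance from full medium and the summed metallothionein test were chosen after results were seen. The number of genes with a different response was 3 at 3 h, 402 at 9 h and 5268 at 24 h. At 9 h the median log2 differences of the lists that passed were 0.21 for ER genes, 0.42 for the integrated stress response, -0.14 for sterol genes, 0.38 for NF-kB genes, 0.22 for FOXO targets, -0.0577 for S phase genes, -0.30 for mitochondrially encoded mRNAs and 0.38 for histone genes. The last 3 had adjusted p = 0.36, adjusted p = 0.68 and adjusted p = 0.37 with an estimated correlation. At 24 h they were 0.94 for ER genes, 1.00 for the integrated stress response, -0.30 for sterol genes, -0.17 for fatty acid synthesis, -0.22 for fatty acid oxidation, 0.52 for NF-kB genes, 0.85 for immediate early genes, 0.26 for FOXO targets, -0.35 for hypoxia and glycolysis, and 0.77 for histone genes. With an estimated correlation, fatty acid oxidation, NF-kB, FOXO, hypoxia and histone lists had adjusted p = 0.072, adjusted p = 0.13, adjusted p = 0.068, adjusted p = 0.24 and adjusted p = 0.37.

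The genes with the largest positive differences at 24 h were MUC12 (5.68), LINC02158 (3.30), FAM157B (3.25), DHRS2 (3.24), LINC00923 (3.10), ACSBG1 (3.06), RASD1 (3.01), CEACAMP10 (2.85), LINC01554 (2.81) and MIR5188 (2.80). Those with the largest negative differences were GK3P (-7.38), AFAP1-AS1 (-4.98), MT-TA (-4.11), KCNH1 (-3.69), MT-TN (-2.94), MAP2K6 (-2.89), MT-TC (-2.85), MRAP2 (-2.74), TMEM255A (-2.73) and MT-TY (-2.70). The MUC12, MIR5188 and GK3P values rest on groups listed at 0, are fitted differences that depend on the pseudocount and measure no fold. MIR5188 stood at 0 in the 3 WT PA libraries. GK3P stood at 0 in the 3 WT BSA libraries, at 25.4, 30.3 and 18.1 in WT with PA, and at 0, 116 and 88.5 in KO with BSA.

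Regrouping PA and BSA labels within each genotype gave at least as many calls in 17, 16 and 12 of 100 groupings at 3, 9 and 24 h, the real one included, with up to 1718, 4657 and 8542 calls in another grouping. By that test chance was not excluded. Unbalanced groupings turn the response shared by both genotypes into a difference, and in the 42 balanced ones the highest counts were 28, 0 and 2. Groups in the balanced ones mix PA and BSA libraries, which widens the spread within groups and can lower the counts. They are therefore no fair reference for the real grouping. After removal of the shared effects, 1, 1 and 1 of 100 regroupings of residuals were as large, the real one itself, with 2, 3 and 3031 calls as the highest of the others, which argues against chance at 9 and 24 h. At 3 h it stays open, since a balanced regrouping of labels called 28 genes and 29 were called without WT BSA replicate 3.

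For comparisons of 3 libraries with 3, there are 10 groupings, too few to reach a p of 0.05, and the real one was the highest in each (1 of 10). For PA against BSA at 3, 9 and 24 h the real counts were 2192, 5236 and 10313 in WT (highest other 10, 2 and 1) and 2258, 5815 and 9595 in KO (0, 1 and 24). For KO against WT they were 5084 in full medium (35), 3907, 4649 and 6235 with BSA (55, 0 and 28) and 4161, 5281 and 7759 with PA (2, 0 and 1). For BSA against full medium they were 2210, 5969 and 10958 in WT (1, 0 and 2) and 3220, 4082 and 9513 in KO (3, 2 and 7). For KO against WT in the mean over 7 conditions, 1 of 100 groupings was as large, the real one with 10845 calls (highest other 1822), which argues against chance.

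At 24 h, WT cells with PA differed less from full medium than WT cells with BSA. Of 8433 WT genes called in both PA against BSA and BSA against full medium, 8207 (97.3%) changed in opposite directions, against 5066 of 6301 (80.4%) in KO. The BSA libraries enter both comparisons, which alone makes them opposed. The covariance in WT was 9.62 times that of simulations with shared libraries and no change, more than noise in those libraries gives. A change particular to BSA medium would also enter both with opposite signs, and the simulations held none. The ratio therefore cannot show that PA moved cells toward full medium. In KO the covariance was 4.43 times that of the simulations. The correlation across genes there was -0.50 both in the data and in the simulations (-0.81 and -0.50 in WT). The noise-corrected mean squared distance from full medium with PA was 0.239 of that with BSA in WT and 1.03 in KO, so PA medium lay nearer to full medium in WT and not in KO.

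Genotype differences of at least 2-fold could reflect gene copy number in chromosome segments that differ between the cells, since whole stretches of chromosomes 8 and 17 were lower in KO. The share of 2-fold genes in windows shifted the same way was 0.126 (65 of 516), so most lay outside such windows, although 4.08% of all genes lay in shifted windows. This share cannot decide on copy number. The runs on chromosomes 8 and 17 had medians of -0.70 and -0.49, short of 2-fold by themselves. Windows of 51 genes also cannot show losses of single genes. The median value of the 2-fold genes in the higher genotype was 30.8, which left low expression undecided. Loss of ADIPOR2 and other differences between clones could not be told apart, and no effect of ADIPOR2 itself on these genes was tested.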

How the results depend on the processing

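The alternatives were planned before the data were examined, apart from the restriction to genes with a mean of at least 50, and every one of them was run. Of 446 alternative values for 23 counts and the ADIPOR2 difference, 423 lay within 1.5 times the reported count, or for ADIPOR2 kept the call (-0.27 rescaled), and 23 did not. Fitting only the groups compared gave 493 genes for PA against BSA in WT at 3 h, 1196 in KO at 3 h, 0 (3 h) and 260 (9 h) for the difference between genotypes, 2024 for KO against WT with BSA at 3 h, 653 for BSA against full medium in WT at 3 h, and 918 and 2532 in KO at 3 and 9 h. For that 0, limma had few residual degrees of freedom by construction, and the fit of all groups and edgeR both called 3 (1398 at unadjusted p below 0.05 in the former). Without the filter the difference was 5 genes at 3 h and 223 at 9 h, and with sample weights 864 at 9 h; the cause was not tested. Leaving out single libraries gave 3 to 29 genes for the difference at 3 h, 199 to 464 at 9 h and 4653 to 5252 at 24 h. The 3 h count was 29 without WT BSA replicate 3, 5 without replicate 1 of WT PA or KO PA and 6 without KO BSA replicate 2. The 9 h count was 199 and 215 without WT BSA replicate 1 and KO BSA replicate 3, 257 and 247 without WT PA replicates 1 and 2, and 222 and 260 without KO PA replicates 2 and 3. It gave 1496 (without KO PA replicate 3) to 1787 for PA against BSA in KO at 3 h and 2104 (without KO full medium replicate 2) to 3295 for BSA against full medium in KO at 3 h, fewer libraries being its construction. Of 32562 alternative values for named genes and list members, 31307 kept direction and side of the threshold, 1099 fell below it, 154 rose above it and 2 changed sign. The sign changed with quantile normalization for HSP90AA1 in KO against WT in the mean over conditions (0.0412) and for GAPDH in BSA against full medium in KO at 9 h (-0.0929); the cause was not tested. Of 1210 alternative list tests, 1057 were the same, 58 were lost and 95 gained. Replicate numbers did not pair libraries (median residual correlation -0.002, 14 of 42 libraries closest to their own number), and blocking on them gave 404 and 5265 genes for the difference at 9 and 24 h. With genes of mean at least 50, the difference was 3, 505 and 5086. Genes with few reads are where depth limits the calls, and in simulation most of the excess of false calls fell there.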

Other observations

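The gene families, zinc genes and gene lengths in this part were chosen after results were seen, apart from the metallothionein prediction, which was written before its values were computed. The summed metallothionein test replaced an earlier test of shared reads, with bounds on SLC30A1 and SLC39A10, after the SLC30A1 change had met neither bound. Genes of C2H2 zinc finger proteins, mostly transcriptional repressors (495 tested), rose with PA at 3 and 9 h. At 9 h 186 rose and 28 fell in WT (median 0.24, adjusted p = 0.00025 with an estimated correlation), and 233 rose and 19 fell in KO (median 0.34, adjusted p = 1.7e-05). At 3 h 72 rose and 10 fell in WT (median 0.14) and 96 rose and 9 fell in KO (median 0.16). In BSA against full medium at 9 h they fell, 155 against 31 that rose in WT (median -0.17, adjusted p = 0.0078) and 109 against 31 in KO (median -0.12). Both other scalings gave medians of the same sign in these comparisons. At 24 h with PA 193 rose and 109 fell in WT (median 0.16, 0.022 with quantile normalization, adjusted p = 0.36 with an estimated correlation), and 219 rose and 62 fell in KO (median 0.25, adjusted p = 0.018). In BSA against full medium at 24 h 144 rose and 165 fell in WT, and 141 and 135 in KO. Rescaled to the same total, 108 rose and 191 fell in WT, and 113 and 149 in KO. The WT median was -0.136 rescaled and 0.094 with quantile normalization, so the direction at 24 h depended on scaling.

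Genes of cytosolic ribosomal proteins (80 tested) were higher in BSA than in full medium at 24 h, with 66 called higher and 5 lower in WT (median 0.44) and 65 and 4 in KO (median 0.36). In KO against WT over the 7 conditions 72 were called lower and 0 higher (median -0.20). With quantile normalization these medians were smaller, 0.22 in both genotypes at 24 h and -0.053 for KO against WT. As a group they did not pass with an estimated correlation (adjusted p = 0.43 in WT at 24 h and adjusted p = 0.33 for KO against WT).

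Metallothioneins, small zinc-binding proteins whose genes are induced by zinc, moved in opposite directions in BSA and PA medium. The summed value in WT was 467 ± 24.6 in full medium, 56.6 ± 9.30 after 24 h with BSA and 420 with PA (mean ± SD, n = 3). One hypothesis is that free zinc fell with albumin, which binds zinc, and rose with palmitate, which lowers that binding. The metallothioneins other than MT1X (MT1F and MT2A) had a median log2 change of -2.28 in BSA against full medium in WT at 24 h. In PA against BSA it was 2.72. The hypothesis predicted both, and as a set these genes passed fry in limma both times. Both comparisons share the BSA libraries, so the second pass adds no separate support. Against full medium, the summed WT value with PA was not higher at 24 h (420 against 467), though it was at 3 and 9 h (574 and 649). MT1F was near the floor (means of 3.05, 0.259 and 7.01 in full, BSA and PA medium), so the result rests on MT2A (341, 46.3 and 314). Any cause that moves metallothioneins together would meet this prediction, so it does not single out zinc and albumin. The summed metallothionein value changed by -3.04. Reads moved between paralogs keep their sum, so they do not account for the fall of the family total. The sum cannot show which paralogs fell. SLC30A1, a zinc exporter also induced by zinc, changed by -0.22 in BSA against full medium and 0.33 in PA against BSA, and SLC39A10, a zinc importer induced when zinc is low, by 1.43 and -1.44. The importer SLC39A4, which is also induced when zinc is low, went the other way (-1.63 and 1.37), and zinc itself was not measured. In KO, MT2A changed by -2.32 in BSA against full medium and 1.89 in PA against BSA and SLC39A10 by 1.58 and -1.87, while SLC30A1 had 0.13 (adjusted p = 0.15) and 0.42, the first of which goes against the hypothesis, as does SLC39A4 (-0.90, and 0.32 with adjusted p = 0.083).

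Across 11812 protein-coding genes with a mean of at least 50, the change from full to BSA medium at 3 h fell with the span of the gene (Spearman rho -0.33 in WT and -0.30 in KO) and with exon length (-0.23 and -0.20). The median log2 change in WT was 0.06 in the 20% of genes with the shortest span and -0.14 in the 20% with the longest. At 9 h rho with exon length was -0.35 in WT and -0.30 in KO.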
